A study of Mus musculus with 4 samples.

How the data were processed

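Gene expression was measured on 4 arrays, each hybridised with biotin-labelled cRNA made from Trizol-extracted total RNA of the colon of male mice, per the labels' protocols. The first pair of arrays came from H2B-GFP mice, which make a histone fused to green fluorescent protein under the control of doxycycline. After 7 days of labelling and 2 days without doxycycline, crypt cells that had kept the label (GFPhigh, non-proliferating) and cells that had diluted it by dividing (GFPlow, proliferating) were sorted by flow cytometry, per the labels. The second pair came from isolated crypts, for which the labels name no sort, of mice carrying a doxycycline-inducible β-catenin gene. One array held crypts of untreated mice (Dox minus), the other crypts of mice given doxycycline at 2.0 mg/ml in the drinking water for 5 days (Dox plus). Each group had 1 array. How many mice each array stands for, and the strain of the mice, are not given in the sources used here.

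The authors deposited 1 log2 expression value per probe set and array for 45101 probe sets. These values had been made with GCRMA, per the submitters' processing notes, a method that subtracts a background modelled from the probe sequences and summarises the probes of each probe set. Its version, and which arrays were processed together, are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 0.47 to 16.27. The medians were 3.38 for GFPhigh, 3.35 for GFPlow, 3.52 for Dox minus and 3.37 for Dox plus, and most probe sets lay in the low range where the background model decides the value. Low values therefore carry little information on abundance, and a floor of 5 was set. GFPhigh had 17412 probe sets at or above the floor, GFPlow 17462, Dox minus 16945 and Dox plus 16982.

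Probe sets were named from a platform annotation. Of all probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none, of which 9160 were not array controls. Probe sets with several symbols or none were not used for gene values. Gene identifiers of 34754 of the probe sets with 1 symbol were found in a current mouse gene table, and 0 symbols needed an update. The result was 18194 named genes, each represented by its probe set with the highest mean over the 4 arrays.

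A gene counted as measured in a comparison when at least 1 of its 2 arrays reached the floor. Values under the floor were set to it, so a difference with 1 array under the floor is a lower bound on the size. Differences are log2 GFPlow minus GFPhigh and log2 Dox plus minus Dox minus, always within a pair. A difference of 1 or more (2-fold) in either direction was counted. With 1 array per group no test between groups was run, and the number of arrays limits the precision of every value.

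The 34 gene lists covered Wnt targets, Wnt antagonists and feedback genes, stem cell markers, S phase genes, G2 and mitosis genes, inhibitors of cyclin-dependent kinases, ribosome assembly, Notch, BMP and hedgehog signalling, and colonocyte, goblet, deep crypt secretory, enteroendocrine and tuft cell markers. They also covered fetal-like epithelium, fibroblasts, smooth muscle, endothelium, T cells, B and plasma cells, myeloid cells, red blood cells and neural cells. The remaining lists held immediate-early and heat shock genes, ATF4 response genes, p53 targets, interferon-stimulated genes, MHC class II, the respiratory chain, fatty acid oxidation, cholesterol synthesis, glycolysis, posterior Hox genes and sex-linked genes. For each list the median difference of the measured members was set against 10000 random lists of the same size matched on deciles of mean expression. The resulting percentile describes these arrays and is not a p-value, because genes are not replicates. Some lists share genes, among them Wnt targets with Wnt feedback genes (8 shared) and with stem cell markers (5 shared).

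Genes are named by a rule with 4 parts. A short set of Wnt, cell cycle and lineage genes is named wherever it was measured. In each comparison, the 10 genes with the largest difference in each direction are named among those at or above the floor on both arrays whose measured probe sets all differ in the same direction. The 5 genes with the highest lower bound in each direction are named under the same condition. Of each list with more than 1 measured gene, 2 to 4 members with the largest absolute differences are named, with any member past 2-fold against the median of its list. The groups, floor, threshold, lists, naming rule and alternative settings were chosen before the data were examined. Genes named outside this rule are said to be so.

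The alternatives were a floor of 4, a floor of 6, no floor, quantile normalization of each pair, a loess correction of the difference on the mean (span 0.4), the mean of a gene's measured probe sets, leaving out probe sets ending in _x_at, _s_at or _a_at, which can match several transcripts, and a 3-fold threshold for the gene sets taken from the GFP pair. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

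The procedure was tested on simulated arrays. Noise was independent between probe sets, with the robust SD of the real differences (0.539 in the GFP pair and 0.496 in the Dox pair). Changed genes were drawn only from genes well above the floor, so their shares do not hold for genes near it. The shares of unchanged genes follow from the assumed noise and are not measured error rates. For GFPlow over GFPhigh, simulated on 9232 genes, 98.0% of genes changed by 2 on the log2 scale and 100.0% of genes changed by 3 passed the 2-fold threshold, as did 6.1% of unchanged genes. For Dox plus over Dox minus, simulated on 9427 genes, both shares were 100.0%, and 4.4% of unchanged genes passed. Among lists of 30 genes, 4 of 100 without a shift lay outside the middle 95% of random lists in each comparison. With a shift of 0.5, 100 of 100 lay outside for the GFP pair and 99 of 100 for the Dox pair. The lists without a shift were drawn from the same genes as the random lists, so their share follows from the design. Many of the real lists had fewer measured genes, whose values can vary together, so the shares with a shift do not hold for them.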

Results

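Expression in the mouse colonic epithelium was profiled on 4 arrays in 2 pairs. One pair set proliferating (GFPlow) against non-proliferating (GFPhigh) crypt cells sorted from normal colon. The other set crypts after 5 days of doxycycline-induced β-catenin (Dox plus) against crypts of untreated mice carrying the same inducible gene (Dox minus). Each group was 1 array, so no difference here has a replicate check. Within each pair the probe set values correlated at Pearson r = 0.985. Across pairs r ranged from 0.930 to 0.941. The pairs also differed in their control probe sets: 18S ribosomal RNA averaged 13.03 (log2) on GFPhigh and 13.29 on GFPlow, against 3.24 on Dox minus and 2.56 on Dox plus. Differences were taken only within a pair. The Y-linked genes Eif2s3y, Kdm5d and Uty were measured in both pairs, with list medians of -0.67 in the GFP pair and -0.10 in the Dox pair (-0.37 with the mean of probe sets), and no Xist probe set reached the floor on any array.

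The first comparison asked how proliferating crypt cells differ from non-proliferating ones. Genes of cell division, Wnt signalling, the stem cell state, ribosome assembly and secretory cells were higher in GFPlow, and genes of absorptive colonocytes and enteroendocrine cells were higher in GFPhigh. All 40 measured G2 and mitosis genes had higher values in GFPlow, with a median difference of 2.12 (4.36-fold), above all 10000 matched random lists. Among them, Mki67, the proliferation marker Ki-67, differed by 2.17 (4.49-fold), and the mitotic kinases Cdk1 and Plk1 by 3.52 and 3.31. Anln, a scaffold of the cytokinetic ring, differed by at least 3.70, since GFPhigh lay under the floor. Of 35 measured S phase genes 25 were at least 2-fold higher in GFPlow and 0 lower, with a median of 1.41. With the floor of 5, the largest values were those of the replication helicase subunit Mcm3 (at least 3.11), Uhrf1 (2.86), the DNA polymerase subunit Pole2 (2.79) and Clspn (2.71). Other members under the floor in GFPhigh have bounds only and could rank higher.

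Wnt target genes had a median difference of 1.23 in favour of GFPlow, above all random lists. Of 12 measured targets, 9 were past 2-fold and 0 lay past 2-fold in GFPhigh. Axin2, a feedback inhibitor and common readout of the pathway, differed by 1.32, Myc by 1.46, Cd44 by 1.88 and the sodium-potassium-chloride cotransporter Slc12a2 by 1.40. Ccnd1 differed by 0.55, or by 1.06 as the mean of its 3 probe sets, and Sox9 by -0.07, or by 0.26 as the mean of its measured probe sets. The stem cell markers Lgr5 and Ascl2 reached the floor in GFPlow only, at 6.25 and 6.45, which gave bounds of at least 1.25 and 1.45. Both bounds dropped under 2-fold, to 0.25 and 0.45, with a floor of 6. The 11 measured stem cell markers had a median of 1.25, with 7 past 2-fold. Among those at or above the floor on both arrays, Smoc2 (3.58, although its second measured probe set gave 0.57), Cdca7 (1.92) and Hopx (1.69) differed most. Lgr5 and Ascl2 have bounds only and could rank above Cdca7 and Hopx. Wnt antagonists and feedback genes showed no common direction. Their 5 measured members had a median of 0.36 at percentile 70.4, with Axin2 and Znrf3 (1.07) higher in GFPlow and the secreted antagonist Sfrp1 (-1.21) higher in GFPhigh. Notum and Wif1 were under the floor on all 4 arrays. All 26 ribosome assembly genes had higher values in GFPlow (median 0.96), 11 of them past 2-fold, among them Wdr12 (2.29), the RNA polymerase I subunit Polr1a (2.20) and the nucleolar protein Nop56 (1.76).

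Goblet cell genes were also higher in GFPlow. Of 19 measured, 10 were past 2-fold and 0 lower, with a median of 1.07 above all random lists (0.69 without probe sets ending in _x_at, _s_at or _a_at). The secretory transcription factors Creb3l4, Spdef and Atoh1 differed by 3.71, 2.94 and 2.64, and Rep15 by 1.65. The goblet genes nearest 0, named outside the rule, were Clca1 (0.01), Tff3 (0.08), Zg16 (-0.09) and Fcgbp (0.35). Deep crypt secretory markers had a median of 1.86 over 6 genes at percentile 99.99, with Kit at 2.90, Pla2g2a at 2.20 and Reg4 at 1.94. Absorptive colonocyte markers lay in the other direction. Their median over 26 genes was -0.77, below all random lists, and 8 were at least 2-fold lower in GFPlow, among them the drug efflux pump Abcb1a (-1.31), the sodium-proton exchanger Slc9a2 (-1.15) and the sodium channel subunit Scnn1a (-1.15). Of 9 enteroendocrine genes 4 were at least 2-fold lower in GFPlow, namely Gcg (-1.88), Tac1 (-1.62), Cpe (-1.26) and Chga (-1.22). The median was -0.70 at percentile 0.09, and -0.40 with a floor of 4.

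Notch genes had a median of 0.27 at percentile 80.3 (0.44 without probe sets ending in _x_at, _s_at or _a_at), with the ligand Dll1 (1.56) and Dtx4 (1.13) past 2-fold and the target Hes1 at 0.21. BMP and hedgehog genes had a median of -0.22 at percentile 10.8 (-0.38 without such probe sets). Smad7 (-1.45), Bmp2 (-1.38) and Smad6 (-1.05) were higher in GFPhigh, and the BMP pseudoreceptor Bambi (1.21) in GFPlow. Among 6 inhibitors of cyclin-dependent kinases, Cdkn2b differed by -0.80, Cdkn1a by -0.75 and Cdkn1b by -0.17, while Cdkn2c was 5.65-fold higher in GFPlow. Their median was -0.17 and their mean 0.11, so the sign of the set was not settled. Interferon-stimulated genes had a median of -0.29 over 16 genes at percentile 1.86, with Mx1 (-2.74 or beyond) and Irf7 (-1.27) past 2-fold. The median was -0.51 with the mean of probe sets, and without probe sets ending in _x_at, _s_at or _a_at it was -0.26 at percentile 4.55, inside the middle 95% of random lists.

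Genes of other cell types were mostly under the floor in the sorted cells. The smooth muscle, endothelial, red blood cell and neural lists had 0 measured genes. The T cell list had only Itgae (1.03), or 3 genes at a median of 0.20 with a floor of 4. The B and plasma cell list had only Ighm (-0.14 or beyond, and -0.56 with a floor of 4). Fibroblast genes were Pdgfrb (-0.28) and Vim (at least 0.18), with a list median of -0.05 that became 0.45 with a floor of 4 and 0.70 without a floor. Myeloid genes had a median of 0.12 over 4 genes, with Laptm5 (at least 0.53) and Cd14 (0.21) furthest from 0, and the median was 0.21 over 7 genes with a floor of 4 and 0.96 without a floor. The tuft cell list had only Avil (-0.13), or 2 genes at a median of 0.02 with a floor of 4.

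Over all 9381 measured genes, 826 were at least 2-fold higher in GFPlow and 403 at least 2-fold lower, of which 125 and 38 were lower bounds. Besides those above, the largest differences in favour of GFPlow were those of Kdelr3 (3.75), a receptor that retains proteins in the endoplasmic reticulum, the short-chain fatty acid receptor Ffar2 (3.62), Plpp1 (3.49), the acyl-CoA thioesterase Acot1 (3.35), the phospholipase Plcb4 (3.32) and the kinetochore gene Spc24 (3.31). Bounds were at least 3.47 for Ptpro, 3.33 for Gatm, an enzyme of creatine synthesis, 3.28 for Gpr20 and 3.26 for Csrp1. In favour of GFPhigh stood the fatty acid binding protein Fabp5 (-3.10, with its second probe set at -1.16), Cyp2d12 (-3.02), Ly6m (-2.85), Rhof (-2.75), Kifc2 (-2.54), Vegfa (-2.53), the tyrosine aminotransferase Tat (-2.47), Ss18l1 (-2.46), the phosphate transporter Slc34a2 (-2.44) and Ifit1bl2 (-2.43). Methig1 (-3.34), Padi4 (-2.80), Gm15666 (-2.45) and Syt11 (-2.35) were under the floor in GFPlow, so these values bound the size from below. A floor of 6 gave -1.65 for Kifc2, -1.80 for Padi4, -1.45 for Gm15666 and -1.35 for Syt11, and the mean of probe sets gave -1.33 for Ifit1bl2. Among called genes with another measured probe set, 399 of 430 had the same direction in it and 223 were also past 2-fold. Of 30 lists with measured genes 13 lay outside the middle 95% of random lists. The 5% of random lists that lie outside is no chance rate for these lists. Members of a fixed list can vary together, and some lists share genes.

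The second comparison asked how crypts able to make extra β-catenin differ after 5 days of doxycycline. The untreated mice had neither doxycycline nor induction, so these cannot be told apart. Ctnnb1, the gene for β-catenin, was high on all arrays. Its strongest probe set read 14.05 in Dox plus and 14.16 in Dox minus, a difference of -0.11, and the others differed by 0.66 and 0.20, which made the mean 0.25. Whether these probes lie in the part of the gene that the transgene holds is not given in the sources used here, so they do not check the labels.

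Wnt target and stem cell genes were higher in Dox plus, and interferon-stimulated and enteroendocrine genes were lower. Lgr5, a receptor and marker of crypt stem cells, read 10.14 in Dox plus and 6.29 in Dox minus, a difference of 3.84 (14.3-fold). Ascl2, a stem cell transcription factor, differed by 2.98 (its 3 probe sets by 2.98 to 5.38), Myc by 2.88, Axin2 by 2.43, Ccnd1 by 1.13 and Sox9 by 0.56, or by 1.07 as the mean of its probe sets. Of 13 measured Wnt targets 8 were at least 2-fold higher and 1, Bambi (-1.20), at least 2-fold lower, with a median of 1.65 (3.14-fold) above all random lists. Among 5 Wnt feedback genes, Axin2 and the receptor ubiquitin ligase Rnf43 (2.10) were past 2-fold, while Znrf3 differed by 0.70 and Sfrp1 by -0.67 or beyond. Their median was 0.71 at percentile 96.7, or 1.40 at percentile 99.9 over 4 genes with a floor of 6. The 13 stem cell markers had a median of 0.59 at percentile 99.9 (1.07 with the mean of probe sets), with 6 past 2-fold, Cdca7 (1.77) and Smoc2 (1.63) among them.

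Ribosome assembly genes were higher throughout. All 26 had higher values in Dox plus, 18 past 2-fold, with a median of 1.12 (2.18-fold) above all random lists. The largest differences were those of Rrp1b (2.60), Nop58 (2.45), Nolc1 (2.01) and Rrp12 (1.96). The 2 cell cycle lists went in opposite directions. S phase genes had a median of 0.54 above all random lists, with 35 of 38 above 0 and 6 past 2-fold, led by the replication licensing gene Cdc6 (1.95), the cyclin Ccne1 (1.64), Mcm10 (1.14) and Cdt1 (1.11). G2 and mitosis genes had a median of -0.67, below all random lists. All 41 had lower values in Dox plus, 6 of them past 2-fold, among them Ckap2 (-1.32), the mitotic kinase Aurkb (-1.24), Nusap1 (-1.15) and Cenpe (-1.09), and Mki67 differed by -0.67. Among cyclin-dependent kinase inhibitors Cdkn2b differed by -1.09, Cdkn1b by -0.54 and Cdkn1a by -0.27, with a list median of -0.24 at percentile 9.22 (-0.41 with a floor of 6).

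Enteroendocrine genes, and to a smaller degree goblet cell and colonocyte genes, were lower in Dox plus, while tuft and deep crypt secretory markers were not lower as sets. All 11 measured enteroendocrine genes were at least 2-fold lower, with a median of -1.91 (3.75-fold) below all random lists. They included the hormone gene Insl5 (-3.66), the serotonin synthesis enzyme Tph1 (under the floor in Dox plus, -3.14 or beyond), the granule protein Chga (-3.00) and Tac1 (-2.67). Goblet cell genes had a median of -0.45 at percentile 0.01, with Retnlb (-1.88), Clca1 (-1.54) and Rep15 (-1.01) past 2-fold and Spdef at -0.99, while Atoh1 read 10.72 on both arrays. Colonocyte markers had a median of -0.29 over 27 genes at percentile 0.13, and Slc9a2 (-1.11) alone was past 2-fold, followed by Slc51b (-0.99) and Tmigd1 (-0.98). Deep crypt secretory markers went both ways. Ang4 (-3.31) and Itln1 (-2.69) were lower and Pla2g2a (at least 2.11) and Mmp7 (1.91) higher, with a median of 0.30 and a mean of -0.27. Tuft cell genes had a median of 0.29 over 6 genes at percentile 73.5 (0.18 with loess), with Alox5ap (at least 0.89) and Plcg2 (at least 0.70) furthest from 0. Notch genes had a median of 0.45 at percentile 95.7, with Lfng (at least 2.05) and Hes1 (1.29) past 2-fold. The Notch median lay outside the middle 95% without a floor (0.64 at percentile 99.2) and without probe sets ending in _x_at, _s_at or _a_at. BMP and hedgehog genes had a median of 0.42 at percentile 97.6 but a mean of -0.01, with Id3 at 1.17 and Bmp2 at -2.81, and the median lay inside the middle 95% of random lists under all 7 alternative settings, at percentiles from 85.0 to 97.3.

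The largest differences between values at or above the floor on both arrays were among interferon-stimulated genes. All 16 measured were at least 2-fold lower in Dox plus, with a median of -3.60 (12.1-fold) below all random lists. The ISG15 protease Usp18 differed by -5.70 (52.0-fold), Rsad2 by -5.52 or beyond, Ifit1 by -4.66, Ifit3 by -4.58, Ifit2 by -4.28 and Zbp1 by -4.16. Their mean level was 11.04 in Dox minus and 7.56 in Dox plus, and lay between these on GFPhigh (9.26) and GFPlow (8.75). Immune and stromal genes that were measured went both ways alongside. The plasma cell gene Jchain (-2.53 or beyond, the only gene of its list measured, with a list median of -0.49 over 3 genes at a floor of 4), the leukocyte gene Laptm5 (-1.53) and the mesenchymal gene Vim (-1.78) were lower, and the myeloid gene Lyz2 differed by 0.71. The myeloid list had a median of -0.06 over 6 genes (-0.18 with loess), the T cell list -0.22 over 4, with Gzmb (-0.26) and Cd8a (-0.26) furthest from 0, and the fibroblast list -1.06 over 2, Vim and Pdgfrb (-0.33 or beyond), or -0.44 over 4 with a floor of 4. Sox10 (0.12) was the only neural gene measured, and the smooth muscle, endothelial and red blood cell lists had 0.

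**Figure D1:**
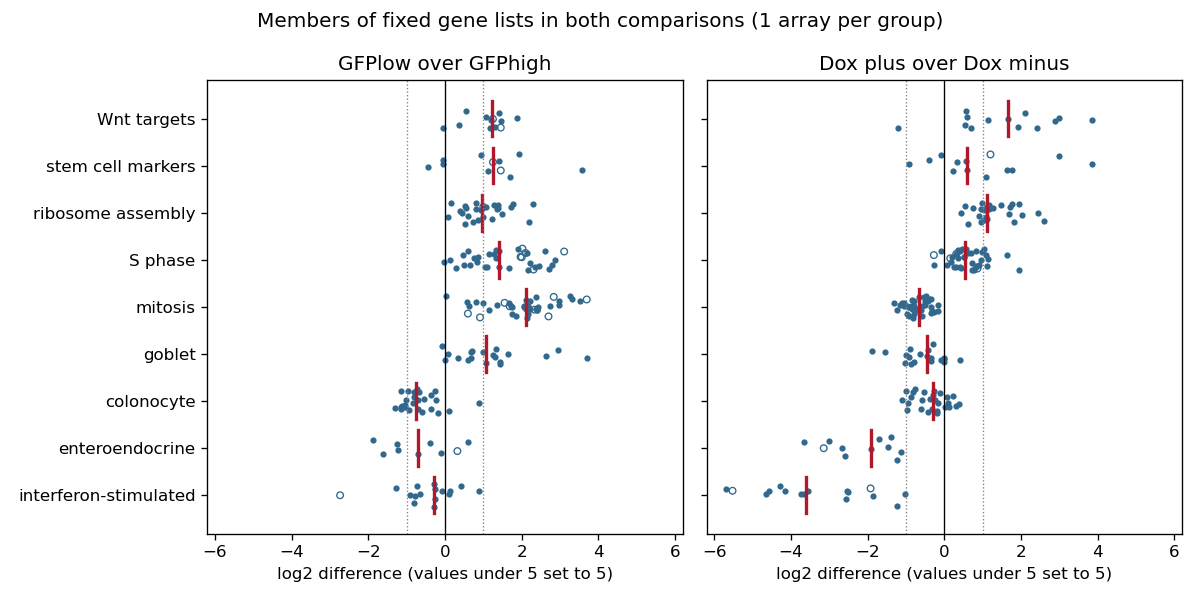
Log2 difference of each measured member of 9 gene lists, GFPlow minus GFPhigh on the left and Dox plus minus Dox minus on the right, with filled points for genes measured on both arrays, open points for lower bounds, red lines for list medians and dotted lines at 2-fold. The mitosis median is 2.12 on the left and -0.67 on the right, and the interferon-stimulated median is -0.29 on the left and -3.60 on the right.

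Over all 9537 measured genes, 661 were at least 2-fold higher in Dox plus and 510 at least 2-fold lower, of which 83 and 65 were lower bounds. The balance depended on the scaling: a loess correction gave 526 higher and 608 lower, a share of 46.4% higher against 56.4% as deposited. Other genes with the largest differences in favour of Dox plus were the secreted phospholipases Pla2g12a (3.53) and Pla2g5 (3.36), the mitochondrial import chaperone Timm9 (3.23), Ier3 (3.01), the myosin light chain Myl7 (2.95), the small nucleolar RNA host gene Snhg5 (2.88) and Pdcd11 (2.83). The highest bounds were those of the MHC class I gene H2-Q2 (at least 8.01), Igfbp4 (at least 4.82, with probe sets from 0.35 to 4.82), the creatine kinase Ckb (at least 4.03), Neto2 (at least 3.62) and Adat2 (at least 3.29). In the other direction stood Ifi202b (-5.41), Ddx60 (-4.81), Trim30a (-4.68), Herc6 (-4.65) and Dhx58 (-4.27), with the bounds Ifi44l (-5.77), Meg3 (-5.58), the pancreatic colipase Clps (-4.69) and Gbp6 (-4.22). The probe sets of Meg3 ranged from -5.58 to -0.04 and those of Ifi44l from -5.77 to -0.09. Among called genes with another measured probe set, 362 of 394 had the same direction in it and 219 were also past 2-fold. Of 31 lists with measured genes 16 lay outside the middle 95% of random lists, and again 5% is no chance rate for such lists.

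The third comparison asked whether genes that separate proliferating from non-proliferating cells also differ after doxycycline. Only genes measured in both pairs were used, so the sets are smaller than the counts of the GFP pair. The 783 such genes at least 2-fold higher in GFPlow had a median of 0.42 between the Dox arrays, above all matched random lists. Of them, 68.1% lay above 0. With a 3-fold threshold in the GFP pair the median was 0.25. Of these, 183 were at least 2-fold higher in Dox plus and 67 at least 2-fold lower, where independent calls would give 50.1 and 37.4. The 343 genes higher in GFPhigh had a median of -0.40, below all random lists, with 14 higher and 72 lower in Dox plus against 21.9 and 16.4 for independent calls. Members of the lists are named here for their calls, outside the rule for named genes. Genes higher in both GFPlow and Dox plus included 5 Wnt targets (Axin2, Lgr5, Ascl2, Myc and Ephb3) and 11 of 26 ribosome assembly genes. Genes higher in GFPlow but lower in Dox plus included the 6 mitosis genes Plk1, Aurkb, Cenpa, Cenpe, Nusap1 and Ckap2, the goblet genes Retnlb and Rep15, and Ang4 and Bambi. Genes higher in GFPhigh and lower in Dox plus included the enteroendocrine genes Chga, Gcg, Tac1 and Cpe, with Bmp2, Slc9a2, Irf7 and Mx1. Across the 9023 genes measured in both pairs, which are not independent replicates, the differences correlated at Pearson r = 0.291 and Spearman rho = 0.389.

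**Figure D2:**
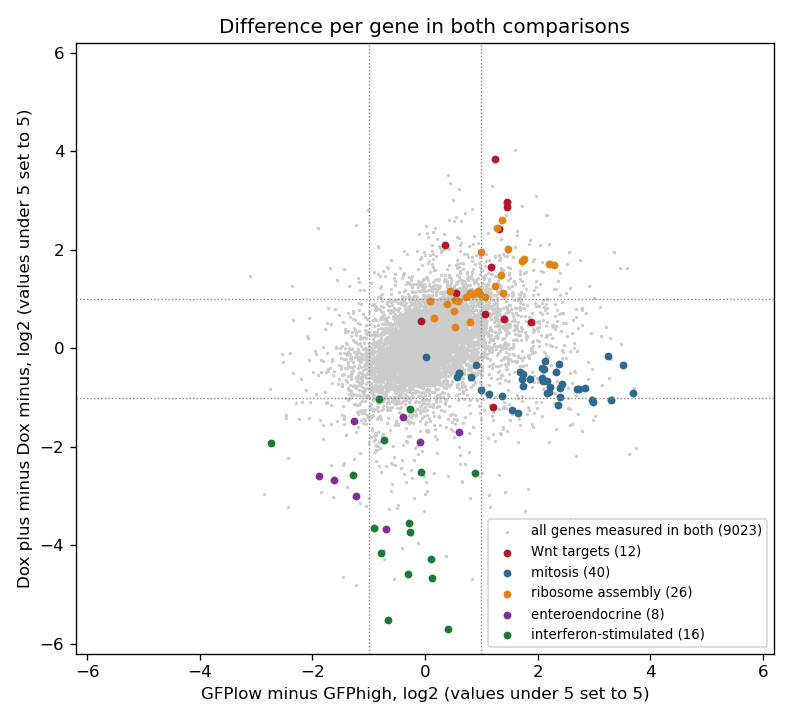
Each point is a gene measured in both pairs, with the log2 difference GFPlow minus GFPhigh on the horizontal axis and Dox plus minus Dox minus on the vertical axis, dotted lines at 2-fold, and members of 5 lists in colour. Wnt target and ribosome assembly genes lie mostly to the upper right, mitosis genes to the lower right with all but 1 of their horizontal values above 0.5, and 1 gene, H2-Q2, lies outside the plotted range.

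**Figure D3:**
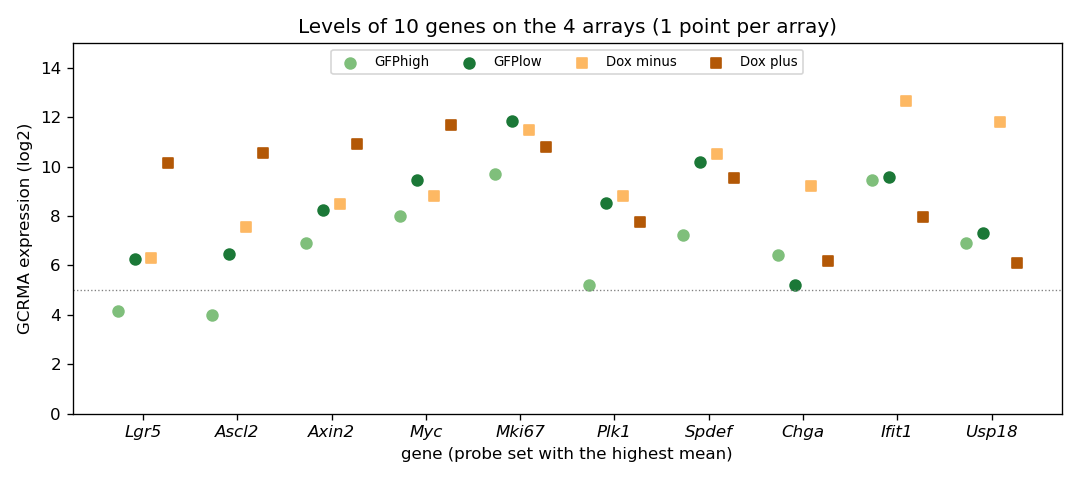
GCRMA log2 level of 10 genes on the 4 arrays, 1 point per array, with circles for the GFP pair, squares for the Dox pair and a dotted line at the floor of 5. Lgr5 reads 4.14 in GFPhigh, 6.25 in GFPlow, 6.29 in Dox minus and 10.14 in Dox plus, while Usp18 reads 6.90, 7.31, 11.80 and 6.10 in the same order, and levels of different pairs were not tested against each other.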

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

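The comparison of control probe sets was chosen only after their values were seen. A signal on control probe sets outside the gene comparisons separated the pairs of arrays. The 18S ribosomal RNA probe sets averaged 13.03 (log2) on GFPhigh and 13.29 on GFPlow, and each of the 3 lay above the highest of them on Dox minus, 3.83. The 24 probe sets for the Bacillus subtilis transcripts dap, lys, phe and thr, usually added to a sample as polyadenylated controls, averaged 11.67 on GFPhigh and 10.97 on GFPlow, and each lay above the highest of them on Dox minus, 3.74. The B. subtilis trp probe sets stayed at 2.61 and 2.59 on the GFP arrays. Hybridization controls averaged 12.21 and 12.04 on the GFP arrays and 10.03 and 9.86 on the Dox arrays. The 3′ minus 5′ difference of Actb was 1.11 and 1.17 on GFPhigh and GFPlow and 0.80 and 0.76 on Dox minus and Dox plus, while that of Gapdh was -0.04 and -0.14 on GFPhigh and GFPlow and -0.02 and -0.12 on Dox minus and Dox plus and did not separate the pairs. No explanation, technical or biological, was tested for these values.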

How the results depend on the processing

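All alternatives in this part were chosen before any result was seen, and none was added later. No paired analysis was possible because each group had 1 array and the labels give no replicate numbers, and no array could be left out for the same reason. All 28 alternative counts of genes past 2-fold stayed within 1.5 times the reported count, and all 140 alternative medians of 10 lists (Wnt targets, stem cell markers, S phase, mitosis, ribosome assembly, colonocyte, goblet, deep crypt secretory, enteroendocrine and interferon-stimulated genes) kept their direction and stayed within the bootstrap interval over their genes. Of the other list medians 269 stayed within that interval and 10 moved beyond it, and 1 that lay outside the middle 95% of random lists as reported changed sign: the MHC class II median of Dox plus over Dox minus became -0.10 without probe sets ending in _x_at, _s_at or _a_at, which left 1 gene. Counting every list, 11 of 420 alternative medians changed sign, and the others of these 11 came from reported medians no further from 0 than 0.209. A bootstrap interval over genes is wide where a list has few genes that differ much. An example is the 7 deep crypt secretory genes of the Dox pair, from -3.31 to 2.11. Staying within the interval says little about such lists. The place of each list among random lists under these alternatives, and sign changes of all lists and named genes, were compared only after the results were seen. Of the lists outside the middle 95%, 2 in the GFP pair and 4 in the Dox pair lay inside it under at least 1 alternative, namely interferon-stimulated and MHC class II genes in the first and BMP and hedgehog, B and plasma cell, MHC class II and posterior Hox genes in the second. The B and plasma cell list had a median of -0.49 over 3 genes with a floor of 4. Of the lists inside it, fetal-like genes in the GFP pair and Wnt feedback, Notch and fibroblast genes in the Dox pair lay outside under at least 1 alternative. Of the named genes 480 alternative values stayed within 1 robust SD of the differences of all genes and 70 moved further. Sox9 in the GFP pair (0.26) and Ctnnb1 in the Dox pair (0.25) changed sign with the mean of probe sets, and Atoh1 in the Dox pair with quantile normalization (-0.04) and loess (-0.06), all from reported values no further from 0 than 0.107. Of the alternative values of the third comparison 26 stayed within the bootstrap interval and 4 moved. The median Dox difference of genes higher in GFPlow moved to 0.31 with quantile normalization, 0.29 with loess and 0.25 with the 3-fold threshold, and that of genes higher in GFPhigh to -0.51 with the 3-fold threshold. The cause was not tested. Signal over background limits Lgr5 and Ascl2 in the GFP pair, where a floor of 6 gave 0.25 and 0.45 and a floor of 4 gave 2.11 and 2.45.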

Other observations

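The tests of cycling cells, of leukocytes and of a single unusual mouse, and the genes singled out by name without a list, were chosen only after the result was seen. ATF4 response genes had a median of 0.78 over 15 genes at percentile 99.97 in the Dox pair, where 6 were at least 2-fold higher in Dox plus and 1 lower, with the serine synthesis enzymes Psat1 (2.38) and Phgdh (1.95) and the transcription factor Atf5 (1.99) higher and Nupr1 (-2.35) lower. In the GFP pair their median was 0.50 over 14 genes at percentile 99.1 (0.79 with the mean of probe sets and 1.10 without probe sets ending in _x_at, _s_at or _a_at), with Phgdh at 2.56, the asparagine synthetase Asns at 1.76 and Aldh18a1 at 1.68. Cholesterol synthesis genes had a median of 0.53 over 15 genes at percentile 99.9 in the Dox pair (0.35 with the mean of probe sets), where 5 were at least 2-fold higher in Dox plus, among them Mvd (2.08), Idi1 (1.30), Lss (1.22) and Srebf2 (1.16), and of -0.01 in the GFP pair, with Fdps (0.35) and Msmo1 (-0.34) furthest from 0. Glycolysis genes had a median of -0.43 in the GFP pair at percentile 0.92, with the glucose transporter Slc2a1 at -0.73 and Pkm at -0.51, and of 0.19 in the Dox pair at percentile 91.4, with Slc2a1 at -0.88 and Pgk1 at 0.82. Respiratory chain genes had medians of 0.00 and 0.08 in the GFP and Dox pairs and 0 of 30 genes past 2-fold in either, with Ndufa4 (0.57) and Uqcrc2 (-0.44) furthest from 0 in the first and Cox5b (-0.44) and Ndufa8 (0.34) in the second. Fatty acid oxidation genes had medians of -0.20 and -0.09 (the latter 0.01 with the mean of probe sets), with Cpt1a, which controls fatty acid entry into mitochondria, at -0.86 and -1.18, followed by Slc25a20 (-0.61) in the GFP pair and Pdk4 (-0.57) in the Dox pair.

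MHC class II genes had a median of -0.64 over 6 genes at percentile 0.27 in the GFP pair, with the transactivator Ciita at -1.76 or beyond and H2-Aa at -0.99. Without probe sets ending in _x_at, _s_at or _a_at, 3 genes were left at a median of -0.72 and percentile 2.98, inside the middle 95% of random lists. Their median in the Dox pair was 0.82 over 4 genes, with H2-Ab1 at 1.43 and Cd74 at 0.91, but -0.10 with such probe sets left out, which kept 1 gene. Immediate-early and heat shock genes had a median of 0.03 in the GFP pair (0.13 with the mean of probe sets), with Hspb1 (2.22) and Klf6 (-1.02) past 2-fold, and of -0.26 in the Dox pair at percentile 0.69 (-0.40 with loess), with Ier3 (3.01) against Nr4a1 (-2.53 or beyond) and Atf3 (-1.52). Targets of p53 had a median of -0.06 in the GFP pair (-0.17 with the mean of probe sets), where the mean was 0.04 and Plk2 (2.11) and Aen (at least 2.01-fold) were past 2-fold, and of -0.21 in the Dox pair at percentile 2.89 (0.02 at percentile 29.0 with the mean of probe sets), with Aen at 1.13 and Fas at -0.98. Genes of fetal-like epithelium had a median of -0.55 over 4 genes in the GFP pair at percentile 2.63 (2.22 to 2.41 with quantile normalization, loess or the mean of probe sets, but 13.5 with a floor of 4), with Anxa8 at -0.88 and Clu at -0.85 against Krt7 at 1.14. In the Dox pair their median was 0.46 and their mean -0.15, with Krt7 (1.37) higher and Clu (-2.06) and Gja1 (-1.38) lower. Posterior Hox genes, which mark position along the gut, had a median of -0.27 in the GFP pair (-0.45 without such probe sets and -0.09 with a floor of 6), led by Hoxa13 (-0.75) and Hoxd11 (-0.56). In the Dox pair the median was 0.93 (0.15 at percentile 54.6 without probe sets ending in _x_at, _s_at or _a_at and 0.50 at percentile 92.6 with a floor of 6) and the mean -0.03, since Hoxa13 (1.58) and Hoxa11 (at least 2.83-fold) were higher and Hoxd13 (-2.95 or beyond) and Hoxb13 (-1.21) lower in Dox plus.

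Mitosis genes were lower and S phase genes higher in Dox plus, although both sets were higher in GFPlow. Array scaling is argued against, because under quantile normalization and loess the mitosis median was at most -0.74, still below all random lists, while the S phase median was 0.49 and 0.47. Fewer cycling cells alone would lower both sets, yet the S phase median was 0.54, above all random lists. That median is part of the pattern itself, so it is not independent evidence. A smaller cycling share stays possible as part of the cause. A candidate explanation that stays open is that the crypt cells of the treated mice spent more of the cycle in G1 and S phase, or made more S phase transcripts per cell, and 1 array per group cannot separate these from a difference between individual mice.

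Interferon-stimulated genes were lower in Dox plus by a median of 12.1-fold. Array scaling left that median at -3.66 or lower, far below all random lists, so it does not account for the pattern. Leukocytes in the Dox minus crypts would bring their own transcripts. The 11 measured leukocyte genes of 36 listed had a median of -0.19 (SD over genes 0.889, from Jchain at -2.53 to Lyz2 at 0.71). This lay above the interferon median by more than that SD. However, their median level in Dox minus was 7.19, so with the floor of 5 their median could not fall as far as the interferon median. The comparison therefore cannot decide whether leukocyte RNA was the source. With 1 array per group, 1 mouse or preparation with an unusual interferon level, such as from an infection, cannot be told apart from an effect of doxycycline or β-catenin.

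Several genes with very large differences in the Dox pair belong to no list. H2-Q2 read 3.79 on Dox minus and 13.01 on Dox plus, and the imprinted gene Meg3 read 10.58 on Dox minus by its strongest probe set and lay under the floor on Dox plus, as did the imprinted genes Dlk1 (7.47 on Dox minus) and Plagl1 (7.89). On GFPhigh and GFPlow the same probe sets read 11.0 and 9.7 for H2-Q2 and 3.01 and 2.97 for Meg3. Those of Dlk1 read 2.08 and 2.10, and those of Plagl1 2.99 and 1.97. For these genes Dox minus was the array that stood apart, although levels of different pairs were not tested against each other. Mice of different genetic background could give such differences in blocks along chromosomes. Of 205 genes past 4-fold outside the interferon list, 46 had another such gene among the 5 nearest measured genes on either side. Only neighbours with a different symbol stem (its opening letters) counted, so adjacent genes named alike could not. Random sets gave a median of 39 with a middle 95% of 24.0 to 54.0 and a 95th percentile of 52.0. A count at or under that percentile was the outcome set beforehand for no such blocks, and 46 met it. The count thus gave no sign of blocks. It cannot exclude them, since a few blocks would add little to it and blocks made only of genes named alike would add nothing. This explanation cannot be told apart from the others. In the GFP pair the count was 47 of 222, with a random median of 46.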
